A study of Homo sapiens with 23 samples.

How the data were processed

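Choroid plexus tissue taken after death was profiled by bulk RNA sequencing in 23 libraries. Per the labels' protocols, RNA was extracted with a column kit, selected for poly(A) tails and made into directional libraries, which keep the strand, by a sequencing company. The authors deposited a table of whole-number counts per Ensembl gene and library, counted with featureCounts 2.0.8 per the submitters' processing notes. The aligner, the genome build, the annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes may have been shared. All 58735 gene identifiers of the table occur in GENCODE release 29 (GRCh38), and 58708 names were identical there. The other 27 names had been turned into dates by a spreadsheet and were restored through their identifiers. Coordinates are those of GENCODE release 29.

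Libraries were placed in the bipolar (n = 10) or control (n = 13) group by their titles and carry the numbers of those titles, 1 to 23 over both groups, so no number pairs a bipolar with a control library. The labels do not say that the libraries come from separate donors, and p-values measure the spread between these samples. No batch, tissue quality or other donor variable was used, because the labels give none. The cytokine array that the series' design names was not analysed here. Genes of the Y chromosome, XIST and TSIX were left out of all totals, tests and tables, which left 58215 genes.

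Totals ran from 17463900 to 27609000 counts per library. Outside the mitochondrial chromosome they ran from 2038540 to 23891100, an 11.7-fold range, so that precision differs between libraries. Spearman correlations between the libraries' log2 CPM had a median of 0.913 over 253 pairs, from 0.758 to 0.969, with 0.918 within and 0.913 between groups. No pair was identical.

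Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter (minimum count 10, total 15), a robust quasi-likelihood fit and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. The filter kept 16112 genes, 13887 of them protein-coding, which held 99.84% of counts. Log2 fold changes are bipolar minus control, and their standard errors follow from the F statistic. CPM values were computed on TMM-scaled library sizes, and log2 CPM use a prior count of 2.

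Before the data were examined, 44 gene lists for cell types, barrier and transport functions, immune and stress pathways, mitochondria, the clock, Wnt signalling and inositol metabolism were fixed, together with the tests, the alternatives and the rule for named genes. The lists hold 661 genes, of which 580 passed the filter. The mast cell list had 3 measured members, under the minimum of 5, and was not tested, so 43 lists were. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated one, and with fry, which asks whether a list's genes move one way. A list score, the mean log2 CPM of its measured members in a library, was compared between groups with a two-sided permutation test of 100000 resamples. Where a group held fewer than 10 libraries all splits were enumerated, as an exact test. List p-values were adjusted over the 43 lists, and members both over all genes and over the list alone.

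The rule named, per direction, the 10 genes of smallest p among those past the threshold, filled to 5 with the next smallest where fewer passed, and the 5 largest changes among those past it with a mean log2 CPM of at least 1. It always named TTR, IL6, IL1B, TNF, CXCL8, CCL2, ICAM1, NFKBIA, SOCS3 and SERPINA3. For each list past camera, or with a member past the threshold, it named up to 4 members with the smallest p. Clone identifiers and receptor segments were skipped in the first parts. VEGFA, HMOX1, RORA, BHLHE40 and NR1D2, which passed adjusted over the list alone, MT-TC and FBXO32 were chosen after their values were seen. One of the genes the rule named is not reported here.

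The alternatives were size factors of the DESeq2 type, no count filter or a stricter one (CPM of 1 in 10 libraries), DESeq2 1.42.0, limma's voom with sample weights, surrogate variables from sva 3.50.0 (5 found), a brain tissue score, an epithelium score or the log2 mitochondrial share as a covariate, a false discovery rate of 0.1, a log2 fold change of at least 1, the median in place of the mean of list members, and each library left out in turn. Chosen after seeing the data were the fit without the 3 libraries that had over 50% of counts on the mitochondrial chromosome, DESeq2 on the genes of the edgeR filter, DESeq2 without replacing outlying counts for MT-TC, and removal of each library's trend on the GC content and length of each gene's longest transcript, which 99.96% of tested genes had a value for.

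The scripts were tested on simulated data. Counts were drawn from the real means and library sizes, independently between genes. Each fold was given to 50 genes with a mean log2 CPM of at least 0, so recovery at lower counts was not measured. edgeR recovered 12% at 1.5-fold, 42% at 2-fold, 82% at 4-fold and 90% at 8-fold, with 1 false call among 114. DESeq2 recovered 18%, 60%, 88% and 92%, with 24 false calls among 153, and voom 14%, 38%, 76% and 86%, with 3 among 110. Of 10 lists shifted 1.5-fold all 10 were found by each list test, and 0 of 10 unshifted lists were, with genes drawn independently of each other. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.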

Results

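Poly(A)-selected RNA was sequenced from post-mortem choroid plexus, the vascular and epithelial tissue of the brain ventricles that secretes cerebrospinal fluid. The 23 libraries fell into 2 groups, 10 from bipolar disorder and 13 from unaffected controls, and their comparison was the only contrast in the labels. The series' title places the question in inflammation of this tissue. Libraries held between 17463900 and 27609000 gene counts, with 22924100 ± 2518430 (SD, n = 10) in the bipolar and 20967900 ± 3242340 (SD, n = 13) in the control group.

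TTR, which encodes the thyroxine and retinol carrier transthyretin, took 12.6 ± 4.78% of counts in bipolar libraries (SD, n = 10) and 15.2 ± 6.14% in controls (SD, n = 13). Transcripts of the mitochondrial chromosome took 34.9 ± 18.2% in bipolar libraries (SD, n = 10) and 27.9 ± 23.4% in controls (SD, n = 13). Neither difference exceeded the spread between libraries in a two-sided permutation test, with p = 0.282 for TTR and p = 0.445 for the mitochondrial share (adjusted p = 0.596 and 0.605 over 10 measures). Mitochondrial transcripts held over 50% of counts in 3 libraries, with 61.9% in control library 2, 88.3% in control library 19 and 84.4% in bipolar library 6. The same libraries had the lowest TTR shares, 5.32%, 0.863% and 1.34%. These 3 libraries were picked by the mitochondrial share itself, so a p-value for that share without them is descriptive only. Without these 3, a comparison chosen after seeing the data, the mitochondrial share was 29.4 ± 5.88% (SD, n = 9) in bipolar and 19.3 ± 9.83% (SD, n = 11) in control libraries. The TTR share was then 13.9 ± 2.85% (SD, n = 9) and 17.4 ± 3.09% (SD, n = 11). Exact permutation tests over those 20 libraries gave p = 0.0155 for the mitochondrial share and p = 0.0185 for TTR, with an adjusted p of 0.0925 for each. Both are shares of the same total, so a higher mitochondrial share lowers that of TTR. Of counts outside the mitochondria, TTR took 19.5 ± 2.60% (SD, n = 9) in bipolar and 21.5 ± 2.97% (SD, n = 11) in control libraries. The same test gave p = 0.122 for that share (adjusted p = 0.239).

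**Figure D1:**
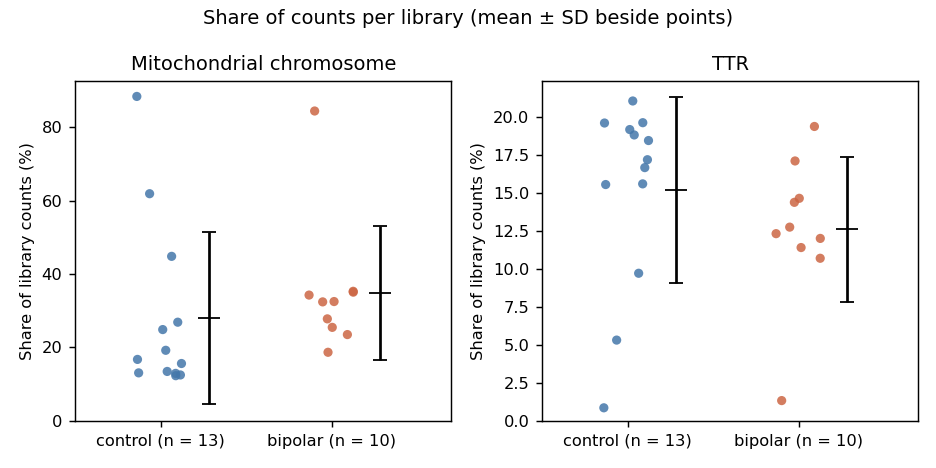
Share of each library's counts (percent, vertical axes) on the mitochondrial chromosome and on TTR, for 13 control and 10 bipolar libraries. Each point is a library, and the bars beside the points are the mean and SD. The mitochondrial share of the 3 libraries over 50% was 61.9%, 84.4% and 88.3%.

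No single gene passed the adjusted threshold between bipolar and control tissue. Of the genes with the smallest p on the higher side, RGS9BP, which anchors the signalling regulator RGS9, stood at 26.9 ± 16.5 CPM (SD, n = 10) in bipolar and 12.3 ± 2.38 CPM (SD, n = 13) in control libraries. Its log2 fold change was 1.13 ± 0.24 (SE), and all 10 bipolar libraries lay above the control median. On the lower side, NR4A2, an orphan nuclear receptor of the immediate early class, stood at 3.48 ± 2.11 CPM (SD, n = 10) against 17.6 ± 18.9 CPM (SD, n = 13), a log2 fold change of -2.33 ± 0.63 (SE), with all 10 bipolar libraries below the control median.

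Other genes with small p on the higher side were FAM13A at 0.85 ± 0.21, PLEKHF1 at 1.93 ± 0.47, NAA16 at 1.05 ± 0.28 and CHAC1, a glutathione-degrading enzyme, at 2.70 ± 0.71 on the log2 scale (SE). PLEKHF1 had medians of 6.43 CPM in bipolar and 3.29 CPM in control libraries, with 49.3 and 36.2 CPM in bipolar libraries 22 and 11. On the lower side they were GRN, which encodes the lysosomal protein progranulin, at -0.58 ± 0.16, ZP3 at -1.22 ± 0.35 and LYRM9 at -0.60 ± 0.17. In GRCh38, per GENCODE release 29, RGS9BP lies on chromosome 19 from 32675407 to 32678300 and NR4A2 on chromosome 2 from 156324432 to 156342348. PLEKHF1 lies on chromosome 19 from 29665056 to 29675457 and CHAC1 on chromosome 15 from 40952962 to 40956519. All are protein-coding genes, and the values are counts over their exons.

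edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 16112 genes higher and 0 lower, with a smallest adjusted p of 0.845 for RGS9BP and of 0.9997 for the other 8 genes above. At an unadjusted p under 0.05 it held 552 genes, 388 higher and 164 lower. Evenly spread p-values would give 805.6. Random splits of the libraries, described under other observations, had a median of 568. limma's voom on the same genes called 0, with 579 genes at an unadjusted p under 0.05. DESeq2, run on all 58215 genes without that filter, called 18 (5 higher, 13 lower), with 1024 at an unadjusted p under 0.05. On the 16112 filtered genes DESeq2 had 714 at an unadjusted p under 0.05. DESeq2 placed RGS9BP (adjusted p = 0.0102), NR4A2 (0.0225), PLEKHF1 (0.0494) and CHAC1 (0.0494) among its calls, while 11 of its 18 lay below the count filter and 7 of those had reads in a single control library. The median standard error of a log2 fold change was 0.29. On simulated counts of the same 16112 genes, drawn independently of each other, edgeR recovered 42% of genes changed 2-fold and 82% of those changed 4-fold. The changed genes all had a mean log2 CPM of at least 0, so these rates do not cover genes of lower counts.

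**Figure D2:**
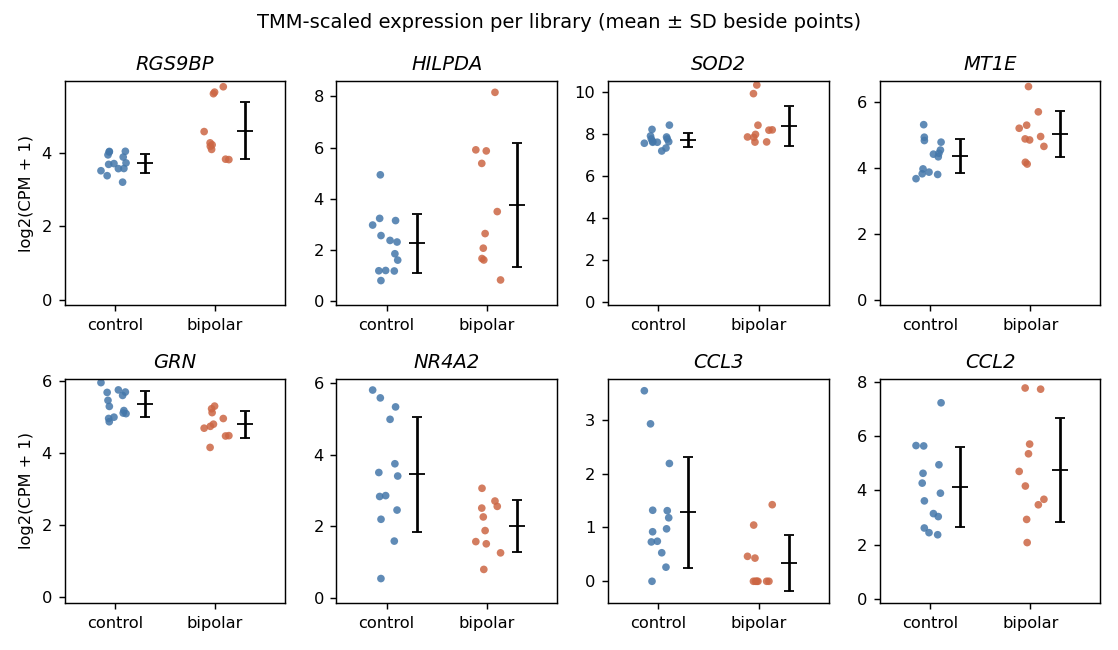
Expression of 8 genes as log2(CPM + 1) (vertical axes) in 13 control and 10 bipolar libraries. Each point is a library, with the mean and SD beside the points. For NR4A2 all 10 bipolar libraries lie below the control median and for GRN 9 of 10 do, and for RGS9BP all 10 lie above it.

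Among the inflammatory genes fixed in advance, the cytokine IL6 had a log2 fold change of 1.24 ± 0.84 (SE) and the monocyte chemokine CCL2 one of 1.05 ± 0.73, while the cytokine IL1B had -1.59 ± 0.92. The neutrophil chemokine CXCL8 stood at 0.47 ± 1.07, the adhesion molecule ICAM1 at 0.34 ± 0.75, NFKBIA, the inhibitor of NF-kB, at 0.32 ± 0.32 and SOCS3, a brake on STAT3 signalling, at 0.53 ± 0.72. TTR stood at -0.13 ± 0.24. None of these 8 passed in edgeR. IL6 averaged 9.07 ± 14.2 CPM (SD, n = 10) in bipolar and 3.83 ± 7.46 CPM (SD, n = 13) in control libraries, and 7 of 10 bipolar libraries lay above the control median. The 95% intervals of the log2 fold changes ran from -0.50 to 2.98 for IL6 and from -0.48 to 2.58 for CCL2. TNF and the acute-phase inhibitor SERPINA3 lay below the count filter and were not tested. TNF had reads in 1 bipolar and 6 control libraries, with at most 19 counts, and SERPINA3 had reads in 6 and 6, with at most 272. All 8 moved by over 1.5 times without at least 1 single library. Without bipolar library 6 the values were 0.62 for IL6, 0.57 for CCL2, 0.23 for SOCS3 and -0.034 for TTR, and they crossed 0 for CXCL8 (-0.66) and ICAM1 (-0.16). Without bipolar library 14 they were 0.75 for IL6, 0.56 for CCL2, 0.24 for SOCS3, 0.17 for CXCL8 and 0.19 for ICAM1. Without control library 2 they were 2.35 for IL6, 1.69 for CCL2, 1.02 for SOCS3, 1.02 for CXCL8 and 1.14 for ICAM1. IL1B stood at -0.47 without control library 10, where TTR stood at -0.080, and TTR at -0.084 without control library 13. Bipolar library 18 left out gave 0.15 for NFKBIA, 0.21 for ICAM1 and -0.23 for TTR, and control library 19 left out gave 0.51 for NFKBIA, 0.94 for CXCL8 and -0.22 for TTR. IL1B, CXCL8, ICAM1 and TTR also took the opposite sign in at least 1 other model, as listed with the alternatives.

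Of the lists of immune genes, 5 passed camera with a preset correlation on the lower side in bipolar tissue and 1, the targets of NF-kB, on the higher side; with an estimated correlation 0 passed. All 10 measured markers of T and NK cells had lower fold changes, with a list score of -1.31 ± 1.46 (SD, n = 10) against -0.23 ± 1.41 (SD, n = 13) in mean log2 CPM. GZMA, a granzyme of cytotoxic lymphocytes, had a log2 fold change of -2.05 ± 0.90 (SE) and TRAC, the constant part of the T cell receptor alpha chain, one of -1.47 ± 0.77. Of 16 measured chemokines 12 were lower and 4 higher, and the scores were 0.89 ± 0.62 (SD, n = 10) and 1.62 ± 0.94 (SD, n = 13). CCL3 stood at -2.63 ± 0.99, CXCL10, an interferon-induced attractant of T cells, at -2.70 ± 1.08 and CCL5 at -1.45 ± 0.64, whereas CCL2 lay on the other side. Several of these genes had few reads. Median CPM in bipolar and control libraries was 0 and 0.97 for CCL3, 0.098 and 0.84 for CXCL10 and 0.12 and 1.07 for GZMA. CCL3 had reads in 4 bipolar and 12 control libraries, CXCL10 in 5 and 11 and GZMA in 6 and 12.

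Of 22 measured complement genes 19 were lower and 3 higher, with scores of 3.31 ± 0.69 (SD, n = 10) and 3.89 ± 0.86 (SD, n = 13). SERPING1, the C1 inhibitor, stood at -0.43 ± 0.16 (SE) and the integrin chain ITGB2 at -1.02 ± 0.51 on the log2 scale. All 11 MHC class II genes were lower, among them CD74 at -0.63 ± 0.47 and HLA-DRA at -0.74 ± 0.56, with scores of 3.06 ± 1.33 (SD, n = 10) and 3.83 ± 1.35 (SD, n = 13). Macrophage markers, a list that did not pass (adjusted p = 0.0812 in camera), were lower in 16 of 17 members, with a median log2 fold change of -0.68 and scores of 2.84 ± 1.35 (SD, n = 10) and 3.39 ± 1.89 (SD, n = 13). C1QA, C1QB and C1QC are members of both the macrophage and the complement list. Some libraries of both groups were low in several of these lists. In control libraries 5 and 8 and bipolar libraries 11 and 16, macrophage scores were -0.42, 0.64, 1.41 and 0.70. In that order MHC class II scored 1.58, 1.80, 1.08 and 1.92, and complement 2.55, 2.53, 2.29 and 2.70. Bipolar library 14, at 1.45 for macrophages, scored 3.52 for MHC class II. The relation between the lists was not tested, so they cannot be counted as separate decreases. Of 28 type I interferon genes 22 were lower and 6 higher. RSAD2 stood at -0.77 ± 0.40 and HERC5 at 0.47 ± 0.23, and the scores were 2.14 ± 0.61 (SD, n = 10) and 2.51 ± 0.31 (SD, n = 13).

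The preset correlation between genes in limma's camera was 0.01. The adjusted p of the 5 lower lists was 0.00149 for T and NK cells (adjusted p = 0.595 with an estimated correlation), 0.00504 for chemokines (0.595), 0.000944 for complement (0.595), 0.0103 for MHC class II (0.631) and 0.0466 for type I interferon (0.631). The score differences were -1.08, -0.74, -0.58, -0.77 and -0.36, with an adjusted permutation p of 0.495, 0.495, 0.495, 0.555 and 0.495. None of their members passed over all genes tested, and 0 passed adjusted over the list alone. The preset call ended without bipolar library 11 or 16 for chemokines (score differences of -0.58 and -0.60), and for MHC class II without bipolar library 11 or 16 or control library 10 or 23 (-0.55, -0.65, -0.61 and -0.62). For type I interferon it ended without any of 12 libraries, with adjusted p up to 0.191, and the difference was -0.20 without bipolar library 6 and -0.21 without the 3 libraries of high mitochondrial share. It also ended with no count filter (-0.35). With surrogate variables in the model the MHC class II and interferon calls ended, at -0.23 and -0.01, and the T and NK cell difference was -0.56 and that of complement -0.26, both still past the preset threshold.

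The targets of NF-kB lay on the higher side, with 17 of 20 measured members higher and 3 lower. SOD2, the mitochondrial superoxide dismutase, stood at 428 ± 379 CPM (SD, n = 10) in bipolar and 217 ± 52.9 CPM (SD, n = 13) in control libraries, a log2 fold change of 0.98 ± 0.29 (SE). PTX3, a secreted pattern-recognition protein, had a log2 fold change of 3.49 ± 1.12 and BIRC3, an inhibitor of apoptosis, one of 1.23 ± 0.45. The list scores were 2.53 ± 0.96 (SD, n = 10) and 2.16 ± 0.75 (SD, n = 13), with a camera adjusted p of 0.0022 (adjusted p = 0.595 with an estimated correlation). SOD2 and PTX3 passed adjusted over the list alone and 0 members over all genes. Each of these 2 lost that call without any of 12 libraries, PTX3 lay below the count filter without 4 others, and SOD2 stood at 0.62 without bipolar library 18. The call ended without bipolar library 6 (score difference 0.21 against 0.37) and with the epithelium score (0.18) or the mitochondrial share (0.09) as a covariate, and without bipolar library 14 the difference was 0.21.

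Hypoxia-induced genes passed camera with the preset correlation (adjusted p = 0.000301) but not with an estimated one (adjusted p = 0.352), with 12 of 15 measured members higher and 3 lower. HILPDA, a lipid droplet protein, stood at a log2 fold change of 3.12 ± 0.87 (SE), ANKRD37 at 1.66 ± 0.51, LDHA, which makes lactate from pyruvate, at 0.88 ± 0.31 and the histone demethylase KDM3A at 0.64 ± 0.21. LDHA averaged 256 ± 189 CPM (SD, n = 10) in bipolar and 139 ± 57.2 CPM (SD, n = 13) in control libraries. List scores were 4.37 ± 0.76 (SD, n = 10) and 3.97 ± 0.34 (SD, n = 13). Of the 15 members 5 passed adjusted over the list alone, these 4 and VEGFA, the endothelial growth factor, and 0 passed over all genes. Without bipolar library 11 none of the 5 passed over the list alone, and ANKRD37 stood at 0.51, HILPDA at 1.88 and VEGFA at 0.55. VEGFA lost that call without any of 14 libraries, LDHA without any of 11 and KDM3A without any of 3. VEGFA stood at 0.53 without bipolar library 22. The score difference of 0.40 had an adjusted permutation p of 0.495.

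Metallothioneins, which bind zinc and copper, were higher in 7 of 8 members, with scores of 3.46 ± 0.88 (SD, n = 10) and 2.77 ± 0.65 (SD, n = 13). MT1E stood at a log2 fold change of 0.78 ± 0.25 (SE), MT2A at 1.38 ± 0.59 and MT1A at 2.58 ± 0.88. MT1A had few reads, from 0 to 3.82 CPM in bipolar and from 0 to 0.822 CPM in control libraries. MT1E and MT1A passed adjusted over the list alone, but not without bipolar library 18, nor MT1A without bipolar library 21. Glucocorticoid-responsive genes were higher in 11 of 12 members, among them CRISPLD2 at 1.88 ± 0.63, ERRFI1, a feedback inhibitor of EGF receptor signalling, at 2.07 ± 0.75 and the kinase SGK1 at 0.44 ± 0.21. Without bipolar library 18 ERRFI1 stood at 1.06 and SGK1 at 0.26, and ERRFI1 stood at 3.15 without control library 19. Genes of the unfolded protein response were higher in 9 of 11 members, and CHAC1, the transcription factor ATF4 (0.50 ± 0.16) and DDIT3 (1.03 ± 0.37) passed adjusted over the list alone. Without bipolar library 14 none of these 3 did, with CHAC1 at 1.75 and DDIT3 at 0.47, and DDIT3 lost that call without any of 8 libraries and ATF4 without bipolar library 6. By contrast 9 of 11 immediate early genes were lower, with IER2 at -0.62 ± 0.29 and EGR2 at -1.49 ± 0.78, and NR4A2 passed adjusted over the list alone. EGR2 stood at -0.85 without control library 19 and at -2.41 without bipolar library 14.

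In camera these lists had adjusted p of 0.00062 for metallothioneins (adjusted p = 0.352 with an estimated correlation), 0.000301 for the glucocorticoid response (0.595), 0.00149 for the unfolded protein response (0.433) and 0.00504 for immediate early genes (0.631). The score differences were 0.69, 0.63, 0.32 and -0.83, with adjusted permutation p of 0.495, 0.555, 0.523 and 0.555, and 0 members passed over all genes. With the mitochondrial share as a covariate the metallothionein and glucocorticoid calls ended, at 0.51 and 0.25. The glucocorticoid difference was 0.35 with the epithelium score in the model. For the unfolded protein response the call ended with surrogate variables (0.22), and the difference was 0.16 without bipolar library 14 and 0.20 without the 3 libraries of high mitochondrial share. For immediate early genes it ended without bipolar library 16 (-0.58), without control library 19 (-0.68) and without the 3 libraries (-0.67), and the difference was -1.26 with the mitochondrial share as a covariate.

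Genes of inositol metabolism, whose monophosphatases lithium inhibits, were higher in 8 of 10 members, with a narrow spread. List scores were 5.20 ± 0.12 (SD, n = 10) in bipolar and 4.97 ± 0.19 (SD, n = 13) in control libraries. ITPK1, an inositol phosphate kinase, stood at a log2 fold change of 0.50 ± 0.19 (SE), SLC5A3, a myo-inositol transporter, at 0.35 ± 0.16 and IPMK at 0.53 ± 0.26. Without bipolar library 22 ITPK1 stood at 0.32. The score difference of 0.23 had the smallest permutation p of the 43 lists, p = 0.00241, and an adjusted p of 0.104. The camera adjusted p was 0.0047 (adjusted p = 0.113 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone.

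Neuron markers were higher in 7 of 10 members. GAD1, which makes the transmitter GABA, stood at a log2 fold change of 0.99 ± 0.34 (SE). It was the only member at an unadjusted edgeR p under 0.05. NEFM stood at 0.91 ± 1.05, NEFL at 0.75 ± 0.9975 and SYP at 0.12 ± 0.245, each within its standard error. The median log2 fold change over the neuron list was 0.099. The scores were 1.07 ± 1.61 (SD, n = 10) and 0.31 ± 1.84 (SD, n = 13), with a camera adjusted p of 0.0022 (adjusted p = 0.595 with an estimated correlation), a difference of 0.76 and, with surrogate variables, 1.25. The 13 protein genes of the mitochondrial chromosome had scores of 12.8 ± 1.10 (SD, n = 10) and 12.1 ± 2.02 (SD, n = 13), a difference of 0.68, and a camera adjusted p of 0.000808 on the higher side (adjusted p = 0.631 with an estimated correlation). Their edgeR fold changes had the opposite sign in all 13 members, with MT-CO1 at -1.18 ± 0.98 and MT-ND1 at -0.88 ± 0.83. MT-CO1 and MT-ND1 were above the control median in 10 of 10 bipolar libraries, and without control library 19 their log2 fold changes were 1.60 and 0.63, while MT-ND1 stood at -1.39 without bipolar library 6. The list difference was 1.07 without control library 19, 0.42 without control library 17 and 0.36 without bipolar library 6, which ended the call. It was 1.06 without all 3 libraries of high mitochondrial share, and 0.08 with the epithelium score as a covariate, where the call also ended. With the mitochondrial share itself as a covariate it was -0.38.

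Nuclear genes of oxidative phosphorylation split evenly, 12 higher and 12 lower, with scores of 7.21 ± 0.18 (SD, n = 10) and 7.15 ± 0.22 (SD, n = 13), a difference of 0.06. COX6C, a subunit of cytochrome c oxidase, stood at a log2 fold change of 0.38 ± 0.11 (SE) and was above the control median in 10 of 10 bipolar libraries. The camera adjusted p was 0.0292 (adjusted p = 0.743 with an estimated correlation). The call ended without control library 1, 8 or 19 or bipolar library 6, 14, 18 or 20, with differences from 0.01 to 0.05, and under 4 other alternatives, among them leaving out the 3 libraries of high mitochondrial share (0.04). The difference was 0.10 without bipolar library 4 and 0.09 without control library 12. Neither the neuron nor these mitochondrial lists held a member that passed over all genes or adjusted over the list alone.

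The remaining 28 of 43 tested lists did not pass. Among cell types, the score of choroid plexus epithelium was 8.22 ± 0.58 (SD, n = 10) in bipolar and 8.44 ± 0.46 (SD, n = 13) in control libraries, a difference of -0.22. The difference was -0.09 for motile cilia, -0.31 for stromal fibroblasts, -0.09 for mural cells, -0.20 for endothelial cells, -0.55 for macrophages, -0.19 for B and plasma cells and -0.42 for neutrophils. It was 0.23 for erythroid cells, -0.17 for oligodendrocytes and -0.04 for astrocytes. Of the barrier and secretion lists, ion transport differed by -0.20, epithelial junctions by -0.20 and retinoid handling by -0.26. Of the immune lists, cytokines differed by -0.04, cytokine and chemokine receptors by 0.17, acute phase and STAT3 by 0.00, the interferon gamma response by -0.41, MHC class I by -0.24, leukocyte adhesion by -0.47 and inflammasome and Toll-like receptors by -0.41. Matrix proteases and inhibitors differed by 0.04, collagens and basement membrane by -0.14, heat shock by 0.08, NRF2 targets by -0.08, ribosomal proteins by 0.04, the circadian clock by 0.16 and Wnt targets by -0.26. Their smallest camera adjusted p was 0.0812, for macrophages and for leukocyte adhesion. Adjusted over the list alone, the haem oxygenase HMOX1 (1.97 ± 0.51) of the NRF2 list passed, as did RORA (0.75 ± 0.22), BHLHE40 (1.35 ± 0.42) and NR1D2 (-0.69 ± 0.24) of the clock list. BHLHE40 stood at 0.81 without bipolar library 11.

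**Figure D3:**
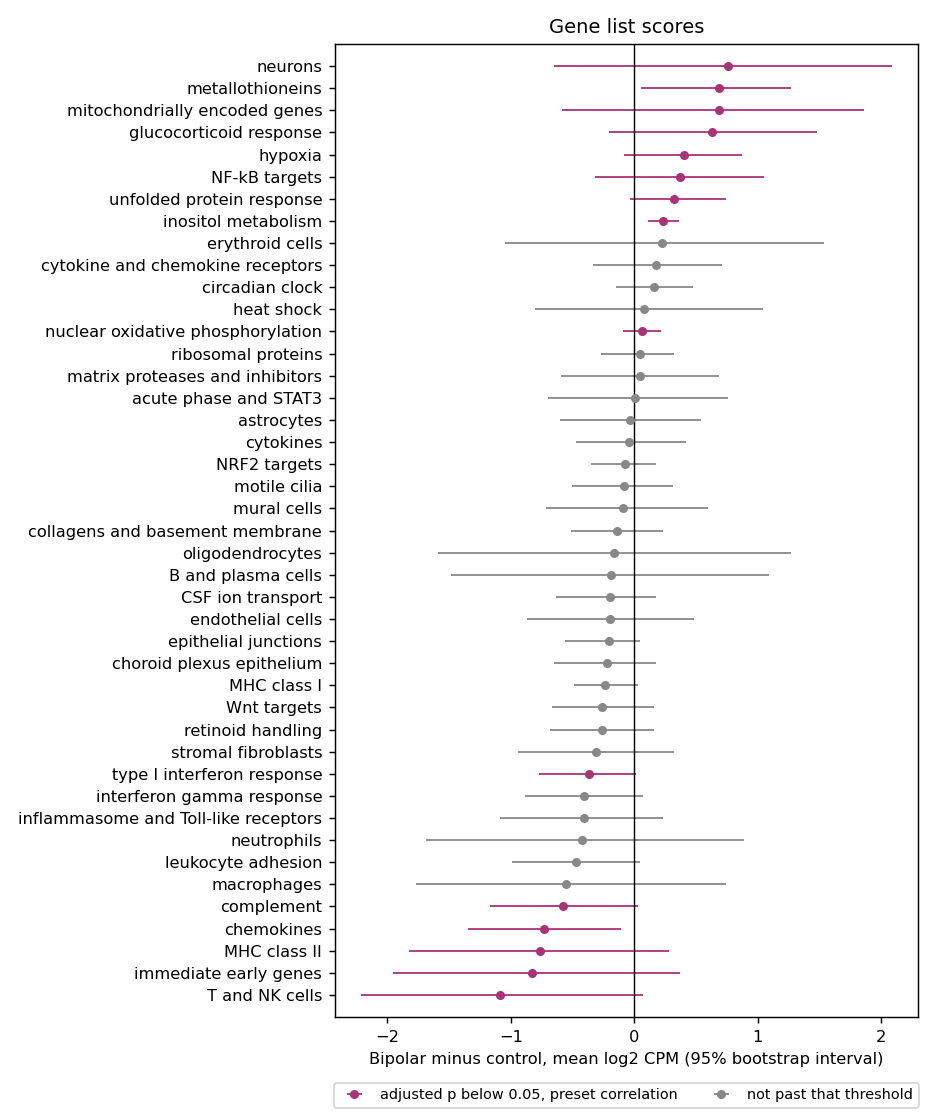
Difference in list score between bipolar and control libraries (horizontal axis, mean log2 CPM of a list's members, bipolar minus control) for 43 gene lists, with 95% bootstrap intervals over 10 bipolar and 13 control libraries. Coloured lists passed camera with a preset correlation, and 0 of the 43 passed with an estimated correlation. T and NK cells have the lowest difference, -1.08.

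Over all lists, 15 passed camera with the preset correlation, 9 higher and 6 lower. With an estimated correlation 0 passed, with fry 0 (smallest adjusted p = 0.246) and with the permutation test of list scores 0 (smallest adjusted p = 0.104). At an unadjusted p under 0.05 the estimated correlation held 4 lists, fry 2 and the score test 3. Of 580 measured list genes, 17 passed adjusted over the list alone and 0 over all genes. Only HMOX1 and NR4A2 of the 17 kept that call without each of the 23 libraries in turn. The median fold change of the members had the opposite sign to the score difference for mitochondrially encoded genes, oligodendrocytes, neutrophils, B and plasma cells, mural cells, astrocytes, cytokines, ribosomal proteins and matrix proteases. Camera's direction differed from the score for cytokines, matrix proteases and B and plasma cells, and for NRF2 targets and collagens the mean fold change was above 0 and the median below it. Metallothioneins, some HLA genes, CCL3 and the haemoglobin genes have near-identical copies whose reads the counting could split, so their values are uncertain.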

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

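The gap tests of single libraries were planned. The tests of respiratory chain genes, of the share without 3 libraries and of the complexity relation without them were chosen only after the result was seen. Within the 10 bipolar libraries, 67 measures were checked for a library that lay far from the others, and 9 had one. Chance gives about 1 in 20 for a single measure. Several of the 67 measure the same thing, such as TTR or mitochondrial content, so the count of 9 cannot be set against that rate. The 13 control libraries were too many for this check, although control libraries 2 and 19 had mitochondrial shares of 61.9% and 88.3%.

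Bipolar library 6 accounted for 7 of the 9. Mitochondrial transcripts held 84.4% of its counts, where the nearest bipolar library had 35.3%, and TTR held 1.34%, where the nearest had 10.7%. Its TMM factor was 0.302 against 0.997. Its list scores were 4.50 against 5.57 for ion transport, 3.26 against 4.63 for epithelial junctions and 15.7 against 13.2 for mitochondrially encoded genes, and its log2 CPM of TTR was 15.4 against 16.7. Bipolar library 21 had 0.608% of its counts on haemoglobin genes, where the nearest had 0.233%. Bipolar library 4 scored 2.91 for NRF2 targets, where the nearest scored 3.65.

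The median mitochondrial share was 32.5% in bipolar and 16.7% in control libraries, with permutation p = 0.445 for the means over 23 libraries and an exact permutation p = 0.0155 (adjusted p = 0.0925) without the 3 libraries over 50%. The last comparison left out libraries by a cutoff on the share itself, 2 of them controls, so its p-value is descriptive only. One candidate explanation of the higher share is RNA of lower complexity, measured as genes detected after thinning each library to 2000000 counts outside the mitochondria. That number was 16414 ± 1323 (SD, n = 10) in bipolar and 17036 ± 1072 (SD, n = 13) in control libraries, with permutation p = 0.235. Spearman's rho of that number with the mitochondrial share was -0.321 (Pearson r = -0.87) over 10 bipolar libraries, with permutation p = 0.367 and 0.031 (adjusted p = 0.367 and 0.031 over 3 relations), -0.582 (r = -0.85) over 13 controls, with p = 0.0405 and 0.00039 (adjusted p = 0.0608 and 0.00117), and -0.49 (r = -0.602) over the 20 libraries of both groups under 50%, with p = 0.0288 and 0.00512 (adjusted p = 0.0608 and 0.00768). Without the 2 farthest libraries of each, rho was 0.262, -0.318 and -0.519 and r was -0.0913, -0.652 and -0.599, so the bipolar relation rests on those libraries, the control relation weakens in rank and the one over both groups stays. The relation over both groups has no term for diagnosis, so part of it can restate the difference between the groups. More respiratory chain per cell is another candidate explanation. The nuclear oxidative phosphorylation score differed by 0.0435 in the 20 libraries (95% bootstrap interval -0.139 to 0.232), where mitochondrially encoded genes differed by 1.06 (0.396 to 1.79). These intervals are too wide to exclude it, so that neither explanation can be told apart from a difference with diagnosis, which stays untested.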

How the results depend on the processing

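All leave-one-out fits were planned, and the tests chosen only after the result was seen were those without the 3 libraries of high mitochondrial share, DESeq2 on the edgeR-filtered genes, the GC and length correction and all tests of MT-TC. The count of genes was 0 higher and 0 lower in edgeR under all its alternatives, each left-out library included, and in voom. DESeq2 gave 5 higher and 13 lower, and 2 higher (MT-TC, RGS9BP) and 1 lower (NR4A2) on the filtered genes, where 714 had an unadjusted p under 0.05. The cause was not tested, though on simulated counts DESeq2 made 24 false calls among 153. Unadjusted counts exceeded 1.5 times the 552 genes with no count filter (5538 of 30314 genes), with surrogate variables (1059) and in DESeq2 on all 58215 genes (1024). They did not in DESeq2 on the filtered genes. The 15 lists past camera became 0 with an estimated correlation and 0 with fry. The first lets the genes' shared variation enter the test, and fry asks whether a list's genes move, not whether they outrank others. Under the other settings, all at a false discovery rate of 0.05, 12 to 18 lists passed, and 13 to 20 without single libraries. The rate of 0.1 was applied to genes only. Of the 15 lists, 11 still passed in the same direction with surrogate variables, 10 with the mitochondrial share as a covariate, 12 with the epithelium score and 12 without the 3 libraries. List scores past the permutation test numbered 0, and between 0 and 1 without single libraries, where inositol metabolism passed without control library 13 or 23.

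Of 2607 alternative values for named genes, 2549 kept their direction and side of the threshold, 6 kept their direction and passed it in DESeq2, and 52 changed sign, over 15 genes and with the cause not tested. Among the 52, those of MT-TC in DESeq2 also passed, over all genes (adjusted p = 0.00289) and on the filtered genes (adjusted p = 0.0143). With surrogate variables the log2 fold changes became 0.33 for IL1B, -0.15 for CXCL8, 0.12 for NKG7, 0.76 for GZMK, 0.57 for CCL4, 0.97 for MT-CO1, 0.72 for MT-ND1, 0.15 for MT-ATP8, 0.51 for MT-ND4L and 1.75 for MT-TC. With the epithelium score they became 0.066 for TTR, -0.40 for CXCL8, -0.28 for ICAM1, 0.75 for MT-CO1, 0.12 for MT-ND1 and 1.05 for MT-TC. With the mitochondrial share they became 0.12 for TTR, -0.64 for CXCL8 and -0.20 for ICAM1, and the mitochondrially encoded list score went to -0.38, a list that measures the covariate itself. DESeq2 gave -0.81 for CXCL8, -0.45 for JUN, 1.58 for MT-CO1, 0.094 for MT-ND1 and 2.38 for MT-TC, and equal values to 2 decimals on the filtered genes. voom gave -0.86 for CXCL8, -0.46 for ICAM1, -0.20 for JUN, -0.15 for MT1X, 1.14 for MT-CO1, 0.93 for MT-ND1, 0.51 for MT-ATP8, 0.79 for MT-ND4L and 1.44 for MT-TC. Without the 3 libraries the values were 1.49 for MT-CO1, 0.98 for MT-ND1, 0.26 for MT-ATP8, 0.72 for MT-ND4L and 3.05 for MT-TC.

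Without single libraries the values ran from -0.66 to 1.02 for CXCL8 and from -0.16 to 1.14 for ICAM1, both lowest without bipolar library 6. They ran from -0.50 (without bipolar library 14) to 0.96 for JUN and from -0.0089 (without bipolar library 20) to 0.22 for SYP. Those highest without control library 19 ran from -1.58 to 1.60 for MT-CO1, -1.39 to 0.63 for MT-ND1, -1.79 to 0.22 for MT-ATP8, -1.95 to 0.67 for MT-ND4L and -4.00 to 3.02 for MT-TC. Of 465 alternative values for the 15 lists, 420 kept direction and side of the threshold, 44 no longer passed and 1 changed sign. No paired analysis was possible because the groups share no library number. Depth limits bipolar library 6 and control library 19 most, with 3211280 and 2038540 counts outside the mitochondria.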

Other observations

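The tests chosen only after the result was seen were those of MT-TC, of the mitochondrial share as a cause of the list calls, of general tissue stress and of the splits for the count of 0 genes, as was the demand that the hypoxia difference clear its bound by the spread between libraries left out. Heat shock genes had fold changes above 0 in 12 of 13 members, among them the co-chaperone BAG3 at 1.52 ± 0.61 (SE, log2) and HSPA1A at 1.36 ± 0.90, while the score differed by 0.08. In the NRF2 list HMOX1 stood at 1.97 ± 0.51 and OSGIN1 at 1.24 ± 0.46, against -1.80 ± 0.91 for SRXN1, and no gene of either list passed over all genes in edgeR.

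MT-TC, the mitochondrial tRNA for cysteine on the minus strand (chromosome MT, 5761 to 5826), had the smallest DESeq2 adjusted p among genes past the edgeR filter, 0.00289 with a log2 fold change of 2.38, while edgeR gave -3.53 ± 1.64 (SE). Medians were 10.7 CPM in bipolar and 2.62 CPM in control libraries, and control library 19 held 2615 CPM, where the next control held 3.89. Without that library edgeR gave 3.02, and DESeq2 without its replacement of outlying counts gave -3.64. FBXO32, a muscle ubiquitin ligase also called by DESeq2 (log2 fold change 2.12, adjusted p = 0.0198), had 0.97 ± 0.74 (SE) in edgeR.

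A set of 100 splits of the 23 libraries into 10 and 13, the real one and 99 drawn at random, was used to ask whether chance can be excluded. No split can give fewer than the real count of 0 genes at the adjusted threshold, so the 100 of 100 that gave as many, the highest other with 1, tell nothing about chance. For the 552 genes at an unadjusted p under 0.05, 52 of 100 gave as many, the real one included, so chance cannot be excluded for their number. The highest other split gave 2399, several times the real count, which may point to a structure of the samples, whose source was not tested.

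The 15 lists past camera were as many or more in 24 of 100 splits, the real one included, with 31 in the highest other, so chance cannot be excluded for their number. A trend on GC content and transcript length per library is argued against, since with it removed all 15 still passed in the same direction. The mitochondrial share as the whole cause of the lists as a set is argued against too. With it in the model the score differences of the 14 other lists kept a median of 0.85 of their size (jackknife 95% interval 0.594 to 1.11), although 2 of the 14 kept under 0.5. This median does not speak for each list. The calls ended for NF-kB targets (0.09), the glucocorticoid response (0.25), metallothioneins (0.51) and nuclear oxidative phosphorylation (0.05), all on the higher side. For these lists the mitochondrial share stays open. A shared variation of genes within lists stays open, because 0 lists passed with an estimated correlation, and a difference with diagnosis stays open as untested.

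The hypoxia list had a score difference of 0.40. Dependence on a single library stays open: without bipolar library 21 the difference was 0.716 of the whole, or 0.707 with the scaling factors refitted, and the shares over all 23 libraries left out in turn had an SD of 0.144. General stress of the tissue may raise all stress lists. Metallothioneins differed by 0.69, the glucocorticoid response by 0.63, the unfolded protein response by 0.32 and NRF2 targets by -0.08. The immediate early score differed by -0.827 (95% bootstrap interval -1.95 to 0.371) and the heat shock score by 0.0774 (-0.806 to 1.04). These 2 intervals reach values close to or above 0.40, so general stress cannot be told apart from an explanation specific to hypoxia. Chance and a difference with diagnosis stay open.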
